A study of Mus musculus with 12 samples.

How the data were processed

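The deposited table, as the authors supplied it, held counts of reads per gene for 49315 genes in 12 libraries, as integers, and these counts were analysed without change. Per the submitters' processing notes, bcl2fastq 2.19, TopHat2 2.0.11 and Cufflinks 2.1.1 were used with the mouse genome build mm9. The role of each tool, the counting program, its gene annotation and the strand that was counted are not given in the sources used here, so antisense reads could not be told apart. Raw reads were not analysed here. Per the labels, RNA was taken with an RNeasy kit and libraries were made with an Illumina stranded total RNA kit with depletion of ribosomal RNA. Gene symbols, chromosomes, gene positions and transcript lengths came from the GENCODE M21 table, whose build differs from mm9. No mm9 coordinates were used, and the neighbours of H2 genes were chosen by their positions in M21. Of the gene identifiers 48988 matched that table and 327 did not, and 30526 genes had at least 1 count.

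Low counts were removed with filterByExpr of edgeR 4.0.16, which left 17051 genes. Libraries were scaled with TMM factors, and all 12 were fitted together with a coefficient per group and the quasi-likelihood F-test of edgeR. Adjusted p-values were from the Benjamini-Hochberg method over all genes tested in a comparison, with 0.05 as the threshold, and a gene is described as called where it passed. All adjusted p-values of single genes are from edgeR unless another tool is named. The standard error of a log2 fold change was its absolute value over the square root of F, without shrinkage, and was not given where a group had no counts. Levels are given as CPM, the counts scaled by library size and TMM factor, with the SD over 3 libraries. The smallest and largest libraries had 12388790 and 18029785 counts. Pairs of replicates gave a Pearson r of log2 CPM between 0.971 and 0.986, and differed by 9.61 to 57.4 times what counting alone would give (chi-square per degree of freedom).

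The comparisons were ATEV with PBS, NTEV with PBS, DNase_ATEV with PBS, ATEV with DNase_ATEV and ATEV with NTEV, with a test for any difference between the 4 groups. Fixed lists of genes, 16 of pathways and 11 of cell type markers, were tested with camera of limma 3.58.1, with a preset correlation of 0.01, for lists with at least 5 measured members, which held for 26 of them. Adjusted p-values of lists were taken over these 26. The comparisons, lists, tests, threshold and most alternatives were fixed before the data were examined. Genes open to being named were, for each comparison, up to 10 each way with the largest fold changes among called genes with a mean log2 CPM of at least 2 and no overlap of the groups, without receptor segments and predicted genes. To these came up to 4 called members of each list with the smallest adjusted p, the 10 genes with the smallest p where fewer than 10 were called, and 16 genes chosen in advance. Other members of lists, and neighbours of H2 genes, were added as examples after the results were seen, and their calls were not followed through the alternatives. Groups with near-identical copies are described as uncertain. Some called genes are not reported here.

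Alternatives were DESeq2 1.42.0, limma voom with sample quality weights, RLE factors, no filter, a filter of CPM over 1 in 3 libraries, a fit of only the groups compared, a block for replicate number, a threshold of 0.1, and each library left out in turn. Lists were tested again with a correlation estimated per list and with fry. A salivary gland score as a covariate, and the most salivary library of each group left out, were added after seeing the data. R 4.3.3, matplotlib 3.10.9 and the R package for tables (version 1.17.8) were used.

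The procedure was tested on simulated data with 200 changed genes per comparison. edgeR found 62.2%, 67%, 66%, 65.7% and 67.7% of genes changed by 1 on the log2 scale and 89.9%, 90.9%, 91.8%, 88.9% and 92% of those changed by 2, in the order of comparisons above. Of its calls 3.85%, 4.85%, 3.11%, 4.38% and 7.02% were false, the last above the 5% aimed at, against 11.9% to 16.6% with DESeq2. A simulated list shifted by 0.5 was found in each comparison, with 0 other lists called by either form of camera. The simulated genes were drawn independently of each other, so false list calls that arise from correlated genes were not tested.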

Results

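The data were counts of RNA sequencing reads per gene in dendritic cells sorted from the cervical lymph nodes of naive wild-type C57BL/6 mice. Dendritic cells take up material, cut its proteins into peptides and display them to T cells on MHC class I and class II molecules. The sort kept cells that carried CD45 (found on leukocytes) and CD11c (high on most dendritic cells) and lacked CD11b. Mice had been injected into a vein behind the eye, every other day and 3 times in all, with PBS, with 50 µg of NTEVs, with 25 µg of ATEVs that held 10 µg of DNA, or with 25 µg of ATEVs that had first been treated with a DNase, an enzyme that digests DNA. The labels write of the DNA as EV-DNA and do not spell out what ATEV and NTEV stand for. The last group is called DNase_ATEV here. Each of the 4 groups held 3 libraries, and the series title sets out to find what ATEVs and their DNA do to the transcription of these cells. The labels do not say whether the replicates came from separate animals or from pools, so the p-values measure only the spread between these samples, which may in part be technical.

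Total counts were 15869248, 16185306 and 13608377 in the PBS libraries, 12818209, 12388790 and 18029785 in the NTEV libraries, 14753851, 12704541 and 15873718 in the ATEV libraries, and 16711838, 17480002 and 14180190 in the DNase_ATEV libraries. Between 22816 and 23809 genes had a count in a library, and 17051 passed the filter on low counts and were tested. In the smallest library 3 counts, the limit that a count of 0 allows, came to 0.242 CPM. The spread between replicates, as the biological coefficient of variation, was 14.4%. The first principal component held 25.6% of the variance and placed the ATEV libraries between 27.9 and 37.7 and the PBS libraries between -39.6 and -26.7, with the DNase_ATEV libraries from -6.13 to 8.23 and the NTEV libraries from -23.1 to 12.1. Transcripts of salivary gland, a tissue that lies beside the cervical nodes, were present in each library at uneven levels. Bpifa2, Amy1 and Smr3a, which code for secreted proteins of that gland, together took 0.595% to 3.60% of counts in PBS, 0.483% to 5.26% in NTEV, 0.156% to 2.41% in ATEV and 0.280% to 3.85% in DNase_ATEV. The second component, with 19.4% of the variance, ranked the libraries much as this salivary signal did (Pearson r = 0.86 over 12 libraries, given as a description without a test).

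Across all 4 groups 409 genes differed (edgeR quasi-likelihood F-test of 3 coefficients, adjusted p under 0.05; 2990 at an unadjusted p under 0.05), and 86 of them belonged to the fixed gene lists. That count was 215 without PBS replicate 2, 230 without PBS replicate 3, 238 without NTEV replicate 1, 671 without NTEV replicate 2, 166 without ATEV replicate 2 and 155 without ATEV replicate 3. It was 1288 with DESeq2, 1025 with limma voom, 1513 with no filter on low counts and 865 at an adjusted p under 0.1.

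The comparison of ATEV with PBS asked what repeated ATEV injection changed in these cells. The genes that load and display peptides rose together. Tap1, a subunit of the transporter that carries peptides into the endoplasmic reticulum, rose from 354.4 ± 27.7 to 2361 ± 266 CPM (SD, n = 3 in each group; log2 fold change 2.74 ± 0.14 SE, adjusted p = 2.53e-07). Psmb8 and Psmb9, catalytic subunits of the immunoproteasome, rose by 2.13 ± 0.11 and 1.78 ± 0.11 on the log2 scale. Of the 22 measured genes of class I presentation 16 rose and none fell, also when adjusted over the list alone (16 up, 0 down), with a list median of 0.86. They included B2m, the invariant light chain of class I molecules (1.08 ± 0.14), the class I heavy chain genes H2-K1 (0.75 ± 0.09) and H2-D1 (0.86 ± 0.09), and Nlrc5, the transactivator of class I genes (1.22 ± 0.18). The 6 not called were Calr, Pdia3, Canx, Erap1, Psme1 and Psme2, with log2 fold changes between -0.13 and 0.18.

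Class II presentation genes were higher as well. Of 16 measured members 11 rose and 1 fell over all genes tested, and 12 rose and 1 fell when adjusted over the list alone, with a list median of 0.78. H2-Ab1, a chain of the class II molecule, rose from 3039 ± 561 to 6427 ± 867 CPM (log2 fold change 1.08 ± 0.18 SE, n = 3 in each group, adjusted p = 0.0075). H2-DMb2, part of the molecule that exchanges peptides on class II, rose by 1.63 ± 0.13, and Ciita, the transactivator of class II genes, by 0.82 ± 0.10. Cd74, the invariant chain, rose from 7870 to 13630.0 CPM (0.79 ± 0.14). The member that fell was Cd209a, a lectin (-0.89 ± 0.13). Ctss, Lgmn, Ifi30 and March1, which act on class II chains or cut antigen, were not called (log2 fold changes from -0.27 to 0.20). Both lists passed the list test (limma camera with a preset correlation, adjusted p = 6.87e-73 and 2.78e-20) and held with an estimated correlation (adjusted p = 5.48e-04 and 0.0214). Beside these genes, markers of NK cells, B and plasma cells and neutrophils rose in the same libraries, with list medians of 1.72, 1.43 and 1.10. Many H2 genes are near-identical copies between which reads can be split, so the values of H2-Q6 (3.52 ± 0.21), H2-Q7 (3.01 ± 0.32), H2-T10 (3.87 ± 0.12) and H2-T24 (2.64 ± 0.18), among others, are uncertain. Of the 27 tested H2 genes 24 rose and 0 fell, and of the 22 list members outside that family 11 rose and 1 fell.

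**Figure D1:**
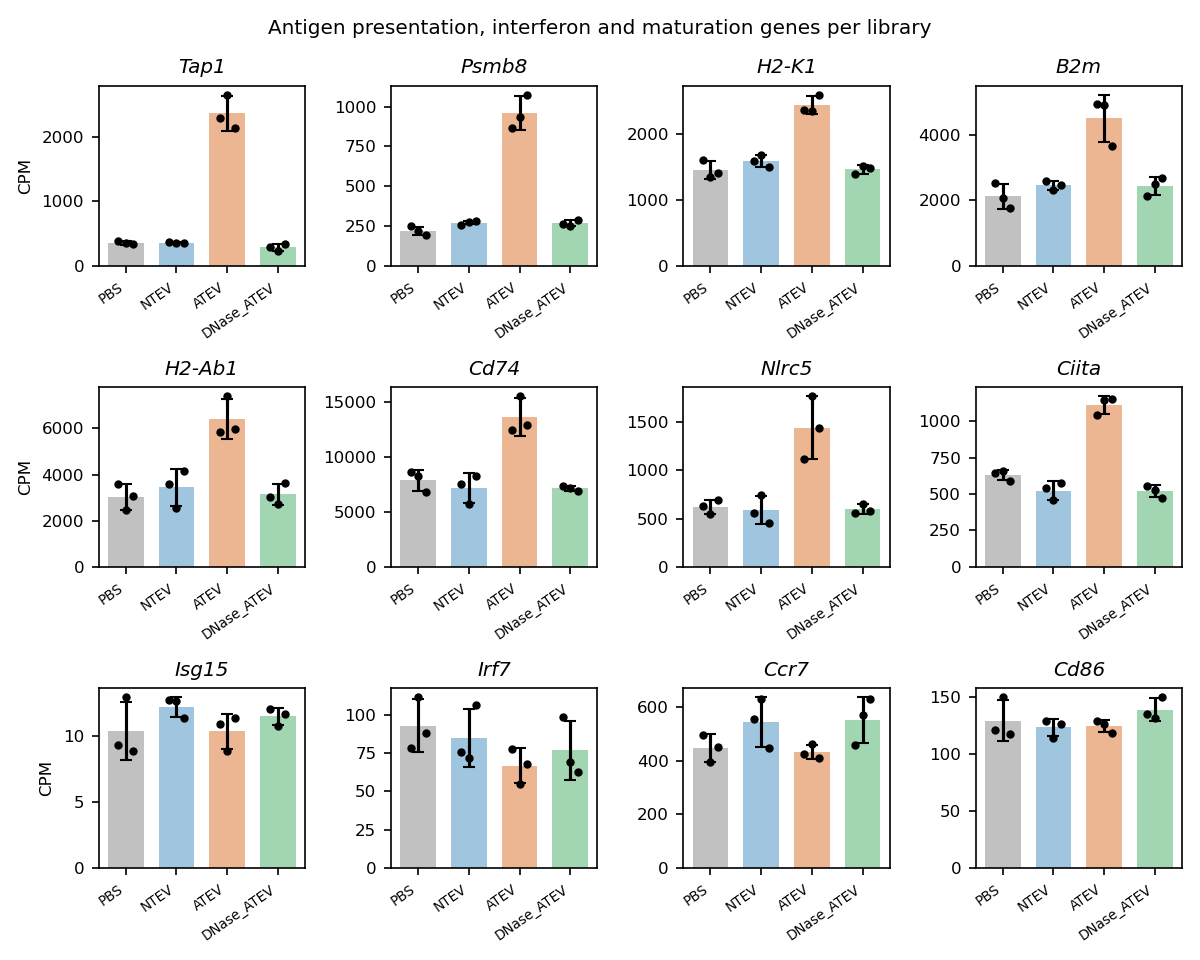
Levels (CPM, vertical axis) of 12 genes in the 4 groups, with bars for the group mean, error bars for the SD of 3 libraries and points for the single libraries. Tap1, Psmb8, H2-K1, B2m, H2-Ab1, Cd74, Nlrc5 and Ciita were higher in the ATEV libraries than in any other library, Tap1 at 2135 to 2654 CPM, whereas Isg15, Irf7, Ccr7 and Cd86 were not called in any of the 5 comparisons.

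Interferon-stimulated genes did not move with them as a group. Of the 34 measured members of the type I interferon list 2 rose and none fell (2 up and 1 down adjusted over the list alone), with Ddx58, the RNA sensor RIG-I, at 0.47 ± 0.09. The other 32 were not called, among them Isg15 (-9.0e-04 ± 0.15), Ifit1 (0.38 ± 0.20) and Irf7 (-0.48 ± 0.20). The list median was -0.0039 while its test pointed up, short of the threshold (adjusted p = 0.303). In the list of interferon gamma and GTPase genes 1 of 21 rose, Gbp7 (0.68 ± 0.18; 1 up over the list alone), with a median of 0.12 (adjusted p = 0.153). Of 20 measured genes of cytosolic DNA sensing 2 rose and 2 fell (4 up and 2 down over the list alone; list adjusted p = 0.59, median 0.034). Zbp1, a sensor of Z-form nucleic acid, rose by 0.51 ± 0.11 and Enpp1, which degrades cGAMP, by 0.81 ± 0.18. Tlr9, the endosomal receptor for unmethylated CpG DNA, fell by 0.64 and Unc93b1, which carries it to endosomes, fell by 0.47, beside the plasmacytoid dendritic cell markers that were lower in the same libraries (median -0.65). Of the 12 fits that left out a library, Tlr9 lost its call in 9 (largest adjusted p = 0.164), Unc93b1 in 8, Gbp7 in 9, Enpp1 in 5, Zbp1 in 4 and Ddx58 in 2. With RLE factors Gbp7 and Unc93b1 were not called either. Neither Cgas (0.14 ± 0.10, adjusted p = 0.48) nor Tmem173, which codes for STING (-0.11 ± 0.12, adjusted p = 0.66), was called.

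The maturation list gave 1 called gene of 27, Il12b, a subunit of IL-12 and IL-23 (0.56 ± 0.14; 1 up over the list alone; median 0.0076, list adjusted p = 0.59), which lost its call in 6 of the 12 fits that left out a library. Ccr7 (-0.046 ± 0.14), Cd40 (0.24 ± 0.11), Cd80 (-0.12 ± 0.10) and Cd86 (-0.053 ± 0.09) were not called. None of 25 inflammatory cytokine and chemokine genes was called by edgeR over all genes or over the list alone (list adjusted p = 0.0524, median 0.31), with Il6 at 0.74 ± 0.40, Tnf at 0.15 ± 0.13 and Cxcl10 at 0.31 ± 0.18. Of 30 cell cycle genes 8 rose, such as Ube2c (0.87 ± 0.19) and Birc5 (0.60 ± 0.12), and 19 rose when adjusted over the list alone. The list was called with the preset correlation (adjusted p = 2.93e-11, median 0.41) and not with an estimated one (adjusted p = 0.225). Of 20 uptake and scavenger receptors 6 rose and 1 fell (8 and 4 over the list alone), with Mertk, a receptor for dying cells, at 0.96 ± 0.14 and Cd93 at 1.35 ± 0.18 (list adjusted p = 6.59e-04, and adjusted p = 0.228 with an estimated correlation; median 0.28). Markers of macrophages (median 0.59, 8 of 17 up) and of stromal and endothelial cells (median 1.15, 7 of 16 up), cells that also express such receptors, were higher beside them (adjusted p = 0.0599 and 0.171 with an estimated correlation). Of 26 immediate early and heat shock genes 3 rose, Jun (0.51 ± 0.08), Rhob (0.43 ± 0.08) and Dnajb1 (0.27 ± 0.06), and 5 over the list alone (list adjusted p = 0.0153, and adjusted p = 0.413 with an estimated correlation; median 0.14). With a library left out, Dnajb1 lost its call in 8 of 12 fits, Ube2c in 4, Birc5 in 3 and Rhob in 1. Dnajb1 also lost it with no filter and with only these 2 groups in the fit.

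Among the metabolic lists, cholesterol biosynthesis was lower (median -0.14, list adjusted p = 5.28e-04, and adjusted p = 0.34 with an estimated correlation), where 1 of 22 genes fell, and 4 over the list alone. No gene of the ribosomal protein list (42 measured) or of oxidative phosphorylation (29 measured) was called, over all genes or over the list alone, with medians of 0.12 and 0.14. Both lists were called up with the preset correlation (adjusted p = 0.0013 and 0.00914) and not with an estimated one (adjusted p = 0.638 and 0.536). The lists of glycolysis and hypoxia (median 0.11, adjusted p = 0.417), of p53 targets (median 0.031, adjusted p = 0.622) and of the unfolded protein response (median -0.041, adjusted p = 0.848) were not called. The first and second held no called gene on either count, and in the last only Hspa5, the chaperone BiP, rose (405 ± 38.0 to 699 ± 65.5 CPM; 0.78 ± 0.14; 1 up over the list alone), a call lost in 1 of the 12 fits that left out a library.

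Dendritic cell markers were lower and markers of several other cell types higher in the ATEV libraries. Of 15 plasmacytoid dendritic cell markers 7 fell and all 15 fell when adjusted over the list alone, with Siglech at -0.91 ± 0.20 and Runx2 at -0.66 ± 0.13 (median -0.65). Of 16 markers of type 1 conventional dendritic cells 3 fell, Clec9a (-0.55 ± 0.08), Flt3 (-0.40 ± 0.07) and Wdfy4 (-0.49 ± 0.12), and 10 over the list alone, and Xcr1 stood at -0.67 ± 0.23 without being called (median -0.42). Both lists were called down with the preset correlation (adjusted p = 6.03e-16 and 1.63e-09) and not with an estimated one (adjusted p = 0.129 and 0.129). Among 12 type 2 markers Itgam, which codes for the CD11b used to exclude cells from the sort, rose from 6.11 ± 0.555 to 12.2 ± 0.458 CPM (0.99 ± 0.14), while Cd209a and Mgl2 (-0.67 ± 0.13) fell (2 up and 3 down over the list alone). The type 2 list was not called (adjusted p = 0.44), with a median of 0.053 and a test that pointed down. The lectins Cd209e (-1.53 ± 0.18) and Cd209d (-0.96 ± 0.17) also fell, outside the lists. The Cd209 genes are close paralogs, and their values are uncertain for that reason. Calls were lost in fits that left out a library for Wdfy4 (7 of 12, largest adjusted p = 0.129), Siglech (5), Runx2 (4) and Mgl2 (3).

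Of 12 NK cell markers 10 rose (11 over the list alone), with the granzyme gene Gzma going from 6.57 ± 1.09 to 66.3 ± 18.1 CPM (3.33 ± 0.30) and Ncr1 at 2.25 ± 0.35. Of 17 B and plasma cell markers 12 rose (15 up and 1 down over the list alone), with Jchain, which joins antibody multimers, going from 62.5 ± 9.79 to 461 ± 64.4 CPM (2.88 ± 0.42) and Bank1 at 1.75 ± 0.26. Of 6 measured neutrophil markers 3 rose (4 over the list alone), with S100a8 at 5 counts over the PBS libraries against 635 over the ATEV libraries (7.005 ± 0.57). These 3 lists held with an estimated correlation (adjusted p = 0.0214, 0.00668 and 0.00413; preset 4.89e-24, 1.56e-22 and 1.68e-11). Macrophage and monocyte markers (8 of 17 up; 12 up and 2 down over the list alone; median 0.59), stromal and endothelial markers (7 of 16 up; 14 up and 1 down over the list alone; median 1.15) and T cell markers (2 of 17 up; 14 up and 1 down over the list alone; median 0.62) were called up with the preset correlation (adjusted p = 4.83e-08, 1.63e-08 and 3.91e-07). With an estimated correlation they were not (adjusted p = 0.0599, 0.171 and 0.239). Epithelial, salivary gland and muscle markers were lower (median -0.48, preset adjusted p = 0.0251, and adjusted p = 0.535 with an estimated correlation), with 0 of 12 called over all genes by edgeR and 1 down over the list alone. With 2 measured members, the erythroid and platelet list was below the 5 needed for a test and held no called gene (median 0.60).

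**Figure D2:**
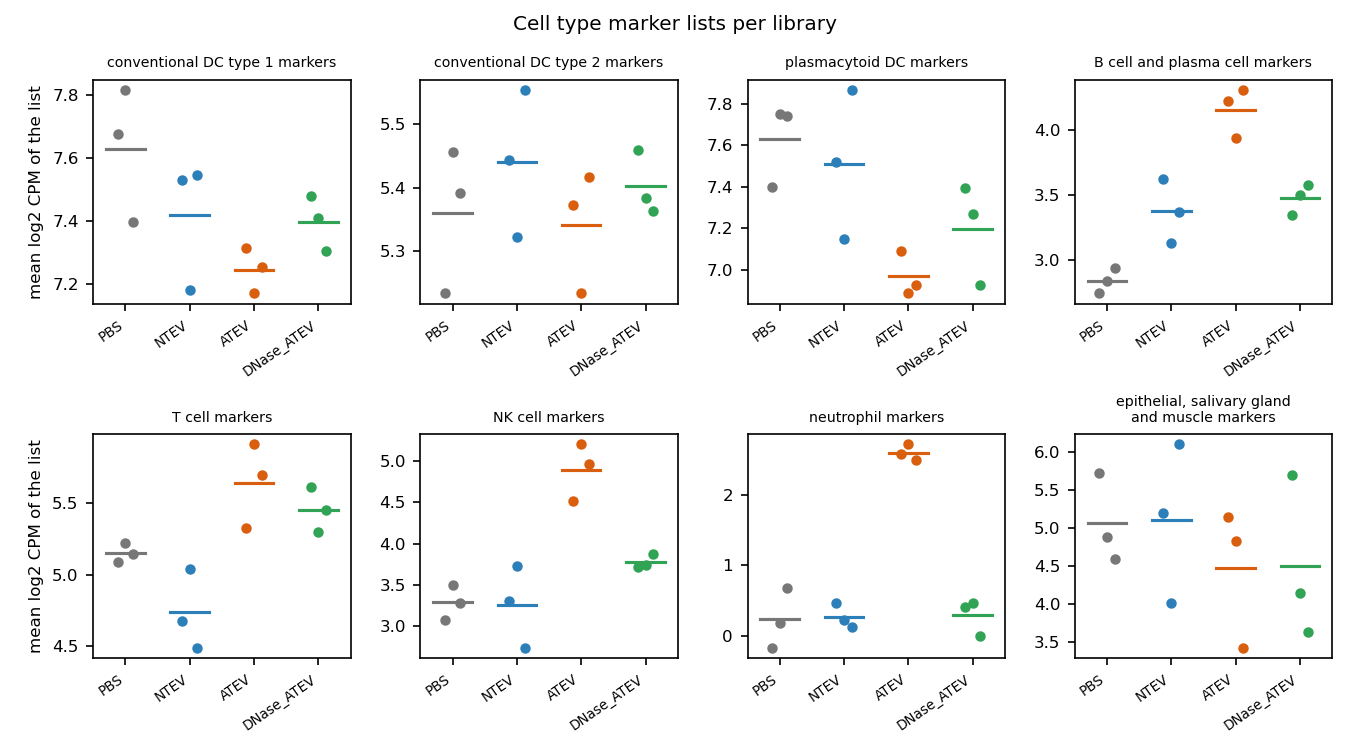
Mean log2 CPM over the measured members of 8 marker lists (vertical axis), with a point per library and a line at the mean of 3 libraries in each of the 4 groups. NK cell markers averaged 4.90 in ATEV against 3.29 in PBS, and neutrophil markers 2.59 against 0.23, while plasmacytoid dendritic cell markers averaged 6.97 against 7.63.

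In all, 542 genes rose and 221 fell in ATEV against PBS (edgeR, adjusted p under 0.05; 3465 genes at an unadjusted p under 0.05), and 310 of the former rose by over 1 on the log2 scale against 12 of the latter. Over all tested genes the groups did not overlap in 26.8%, against 10% by chance. Immunoglobulin and T cell receptor segments made up 63 of the genes that rose and 1 of those that fell. The called count was 228 without PBS replicate 2, 232 without PBS replicate 3, 383, 340 and 372 without ATEV replicates 1, 2 and 3, and 1360 without NTEV replicate 3, which is in neither group but entered the filter on low counts (17353 genes tested without it) and the shared estimate of spread. It was 1346 with DESeq2, 1488 with limma voom, 1586 with no filter on low counts, 1235 with only these 2 groups in the fit and 1590 at an adjusted p under 0.1.

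The comparison of NTEV with PBS asked the same of the other vesicle preparation, given at 50 µg. Immunoglobulin genes made up 8 of the 9 genes that rose, and none fell. Ighg2b, a constant region of IgG, rose from 30.7 ± 10.6 to 186 ± 53.1 CPM (log2 fold change 2.59 ± 0.34 SE, n = 3 in each group, adjusted p = 0.0233), Igkv1-117 by 4.95 ± 0.69 and Iglv1 by 3.40 ± 0.43. The segments resemble each other closely, and reads can be split between them. The remaining gene was Inmt, which codes for an amine N-methyltransferase, with 7.77 ± 0.584 CPM in PBS and 21.8 ± 5.08 in NTEV (1.48 ± 0.23, adjusted p = 0.0488). Igkv3-1 was listed at 0 counts in the PBS libraries and at 2.58 ± 1.23 CPM in NTEV, and was not called (adjusted p = 0.0536). Inmt lost its call in 8 of the 12 fits that left out a library (largest adjusted p = 0.311), Igkv1-117 in 5, and Ighg2b and Iglv1 in 4 each. Inmt also lost it with a filter of CPM over 1. No gene of presentation was called over all genes, and H2-Ab1 stood at 0.18 ± 0.18. The class I list had a median of 0.12 with 0 members called (5 up over the list alone) and was called up as a list (adjusted p = 0.00151, and adjusted p = 0.408 with an estimated correlation). The class II list had a median of 0.023 with 0 called on either count and was not called (adjusted p = 0.902). Isg15 (0.23 ± 0.15), Cd86 (-0.068 ± 0.09), Xcr1 (-0.42 ± 0.23) and Siglech (-0.26 ± 0.20) were not called.

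Ribosomal protein genes (median 0.32) and oxidative phosphorylation genes (median 0.31) lay higher in NTEV than in PBS, with 42 of 42 and 28 of 29 measured members above 0. None was called over all genes, and 35 and 20 were called up when adjusted over the list alone. Of 26 lists 9 were called up and 2 down with the preset correlation, the ribosomal list with the smallest adjusted p (4.77e-31). With an estimated correlation none was called (smallest adjusted p = 0.243), and fry called 0 for a shift one way. T cell markers were lower (median -0.46, adjusted p = 3.96e-09, and adjusted p = 0.287 with an estimated correlation), and B and plasma cell markers higher (median 0.52, adjusted p = 2.35e-06, and adjusted p = 0.243 with an estimated correlation). Over all genes 9 were called by edgeR and 2160 had an unadjusted p under 0.05. The count was 1 without PBS replicate 1 or without NTEV replicate 1, 0 without PBS replicate 2 or 3, 21 and 37 without NTEV replicates 2 and 3, 5 without ATEV replicate 3, and 30 and 58 without DNase_ATEV replicates 2 and 3. DESeq2 called 254 genes, limma voom 54, the fit with no filter 347 and the fit of these 2 groups alone 35, and 49 passed an adjusted p under 0.1.

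The comparison of DNase_ATEV with PBS asked what remained of the change after the DNase step. The presentation genes lay close to PBS. Tap1 was at 286 ± 58.8 CPM in DNase_ATEV and 354.4 ± 27.7 in PBS, H2-Ab1 at 3139 ± 459 and 3039 ± 561 (0.047 ± 0.18), and the medians of the class I and class II lists were 0.064 and -0.022, with 0 of 22 and 0 of 16 members called on either count. No gene was called by edgeR (smallest adjusted p = 0.131), although 2305 had an unadjusted p under 0.05, and limma voom called 0 and DESeq2 255. The 10 genes with the smallest p included Rgs16, a regulator of G protein signalling, at 5.64 ± 0.44 CPM in PBS and 13.0 ± 1.59 in DNase_ATEV (1.20 ± 0.18, adjusted p = 0.131), Rps27 (0.60 ± 0.10), Rpl27a (0.49 ± 0.09), Dnajb1 (0.39 ± 0.06), Dctn3 (0.44 ± 0.07), Usmg5 (0.59 ± 0.10), Rpgrip1 (-0.65 ± 0.11) and Fcmr (1.64 ± 0.29). The others, Hist2h4 (0.81 ± 0.12) and Gm2000 (0.74 ± 0.12), and the ribosomal protein genes have near-identical copies or pseudogenes and are uncertain. Il12b (0.47 ± 0.14), Irf7 (-0.27 ± 0.20) and Siglech (-0.58 ± 0.20) were not called.

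As in NTEV, ribosomal protein genes (median 0.29, 42 of 42 above 0, 29 up over the list alone) and oxidative phosphorylation genes (median 0.23, 28 of 29 above 0, 11 up over the list alone) lay higher in DNase_ATEV than in PBS. B and plasma cell markers had a median of 0.77 (10 of 17 up over the list alone), NK cell markers of 0.46 (1 up over the list alone) and plasmacytoid dendritic cell markers of -0.41 (10 of 15 down over the list alone), with 0 called over all genes. With the preset correlation 13 of 26 lists were called up and 3 down, with an estimated correlation 0 (smallest adjusted p = 0.146, also for B and plasma cell markers), and fry called 4. The count of called genes was 1 without NTEV replicate 2 or 3 and 9 without DNase_ATEV replicate 2, and 358 with no filter on low counts. Without the library of each group that held the most salivary transcripts (PBS replicate 1, NTEV replicate 3, ATEV replicate 1 and DNase_ATEV replicate 1), a setting chosen after seeing the data, it was 397.

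The comparison of ATEV with DNase_ATEV held the vesicle dose at 25 µg and asked what the DNase step took away. Presentation genes were again the leading group, and each of the 27 class I and class II members that rose against PBS also rose against DNase_ATEV. Tap1 was 3.04 ± 0.14 higher on the log2 scale (2361 ± 266 against 286 ± 58.8 CPM, SD, n = 3 in each group, adjusted p = 1.06e-07), Psmb8 1.84 ± 0.10, Psmb9 1.69 ± 0.11, Ciita 1.10 ± 0.10 and H2-Ab1 1.03 ± 0.18 (adjusted p = 0.026). Of 22 class I genes 16 were higher and 0 lower (16 and 1 over the list alone; median 0.90), and of 16 class II genes 11 were higher and 1, Cd209a, lower (11 and 1 over the list alone; median 0.84). The list tests gave adjusted p = 6.69e-127 and 3.68e-44, and adjusted p = 1.08e-04 and 0.00296 with an estimated correlation. Beside them NK cell markers (median 1.31; 5 of 12 up, 10 over the list alone; Gzma 2.14 ± 0.28), neutrophil markers (median 1.30; 2 of 6 up, 4 over the list alone; S100a8 6.61 ± 0.54) and B and plasma cell markers (median 0.60; 1 of 17 up, Pou2af1 at 0.82 ± 0.15, 6 over the list alone) were higher, and held with an estimated correlation (adjusted p = 0.024, 0.00112 and 0.0281). The 8 genes that were lower were Cd209e (-1.82 ± 0.18), Mgl2 (-1.03 ± 0.13), Cd209d, Cd209a, Cd207 (langerin, -0.84 ± 0.13), Cacnb2, Trf and Sowahc (-0.33 ± 0.06). Trf and Cd209d lost their calls in 9 of the 12 fits that left out a library, Pou2af1 in 6 (largest adjusted p = 0.181), Sowahc in 5, H2-Ab1 (largest adjusted p = 0.173), Cacnb2 and Cd207 in 4 each and Cd209a in 2. Trf was not called with RLE factors, nor Cacnb2 with only these 2 groups in the fit. Sowahc lost its call in 1 other alternative chosen in advance, and Sowahc and Cacnb2 each in 1 setting added after seeing the data.

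Interferon, maturation and DNA sensing genes did not separate these groups: Isg15 (-0.15 ± 0.15), Ifit1 (0.065 ± 0.20), Cgas (0.052 ± 0.10), Tmem173 (7.0e-04 ± 0.12), Ccr7 (-0.35 ± 0.14) and Cd86 (-0.16 ± 0.09) were not called. Itgam was 1.07 ± 0.14 higher. Hspa5 was 0.77 ± 0.14 higher, with its call lost in 6 of the 12 fits that left out a library (largest adjusted p = 0.198). Plasmacytoid dendritic cell markers were lower as a list (median -0.24, adjusted p = 1.93e-04, and adjusted p = 0.415 with an estimated correlation), with 0 of 15 called on either count. In all 88 genes were higher and 8 lower (edgeR; 1211 at an unadjusted p under 0.05), the groups did not overlap in 12.8% of all tested genes (10% by chance), and 25 of those higher were immunoglobulin or T cell receptor segments. Of 26 lists 10 were called up and 7 down with the preset correlation, and 5 up and 0 down with an estimated one. The gene count was 63 without ATEV replicate 2, 53 without ATEV replicate 3, 55 without DNase_ATEV replicate 1 and 45 without DNase_ATEV replicate 2, and 169 with DESeq2 and 217 with no filter.

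The comparison of ATEV with NTEV set the vesicle preparations against each other at different doses, 25 and 50 µg, so that preparation and dose cannot be separated. The same 27 presentation genes were higher in ATEV. Tap1 was 2.72 ± 0.14 higher (2361 ± 266 against 358 ± 5.90 CPM, n = 3 in each group, adjusted p = 3.56e-07), Psmb8 1.82 ± 0.10 and Ciita 1.09 ± 0.10. In the class I list 16 of 22 genes were higher and 0 lower on either count (median 0.78; adjusted p = 2.61e-65, and adjusted p = 0.00123 with an estimated correlation), and in the class II list 11 of 16 were higher and 1 lower (11 and 2 over the list alone; median 0.81; adjusted p = 1.15e-24, and adjusted p = 0.0124 with an estimated correlation). Markers of NK cells (10 of 12 up on either count; median 1.77; Gzma 2.52 ± 0.28), T cells (14 of 17 up, 15 over the list alone; median 1.06; Cd3e 1.14 ± 0.18), B and plasma cells (5 of 17 up, 11 up and 1 down over the list alone; median 0.91; Pax5 1.52 ± 0.28) and neutrophils (3 of 6 up, 4 over the list alone; median 1.18) were higher as well. These lists held with an estimated correlation (adjusted p = 0.0124, 0.0263, 0.0263 and 0.00452). Pax5 lost its call in 2 of the 12 fits that left out a library, and Cd3e with only these 2 groups in the fit (adjusted p = 0.0629).

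Lower in ATEV than in NTEV were Cd209e (-1.17 ± 0.18), Cd207 (-0.96 ± 0.14), Mgl2 (-0.90 ± 0.13) and Dntt, which codes for the terminal transferase of lymphocyte precursors (-1.05 ± 0.24). Plasmacytoid dendritic cell markers had a median of -0.57 (1 of 15 down, Ptprs at -0.48 ± 0.10; 15 down over the list alone; adjusted p = 7.28e-13, and adjusted p = 0.228 with an estimated correlation). Isg15 (-0.23 ± 0.15), Irf7 (-0.35 ± 0.20), Cd40 (-0.016 ± 0.11), Tmem173 (-0.051 ± 0.12) and Siglech (-0.65 ± 0.20) were not called, and Ikbke, a kinase that acts with TBK1, was 0.92 ± 0.20 higher. Dntt lost its call in 8 of the 12 fits that left out a library (largest adjusted p = 0.144), Ptprs in 5 and Ikbke in 4. All 3 lost it with only these 2 groups in the fit. The log2 fold change of Dntt ranged from -1.29 to -0.65 over all settings. In all 378 genes were higher and 56 lower (edgeR; 2651 at an unadjusted p under 0.05), with no overlap of the groups in 19.99% of all tested genes (10% by chance) and 16 immunoglobulin or T cell receptor segments among those higher. Of 26 lists 10 were called up and 6 down with the preset correlation, and 6 up with an estimated one. The gene count was 192 and 181 without NTEV replicates 1 and 3 and 176 and 169 without ATEV replicates 2 and 3. It was 683 with DESeq2, 966 with limma voom, 800 with no filter, 91 with only these 2 groups in the fit and 737 at an adjusted p under 0.1.

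**Figure D3:**
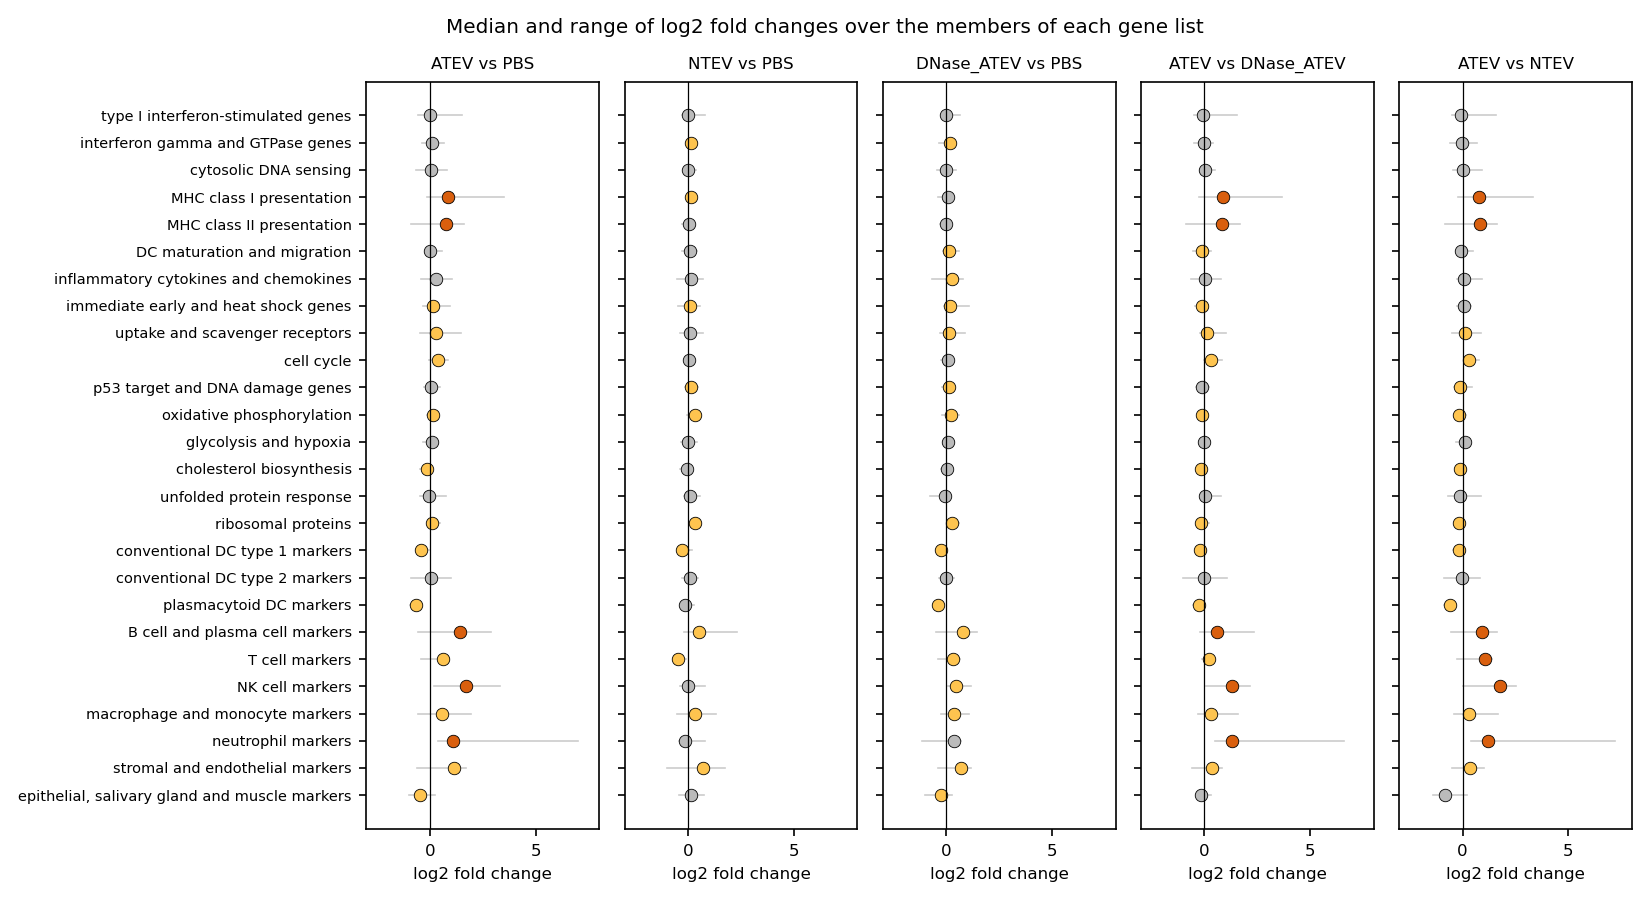
Log2 fold changes (horizontal axis) of the 26 tested gene lists (vertical axis) in the 5 comparisons, one panel each, with a point at the median and a grey line over the range of the members. Dark orange marks lists called with an estimated correlation, yellow those called only with the preset one and grey the rest; MHC class I presentation had medians of 0.86, 0.90 and 0.78 in the comparisons of ATEV with PBS, DNase_ATEV and NTEV, and of 0.12 and 0.064 in those of NTEV and DNase_ATEV with PBS.

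ATEV stood apart from the 3 other groups at once in 66 genes, of which 61 were higher and 5 lower in each of the comparisons with PBS, NTEV and DNase_ATEV. The 5 were Cd209a, Cd209d, Cd209e, Cd207 and Mgl2. With only the ATEV and NTEV groups in the fit Cd209a and Cd209d were not called between them. Of the 542 genes that rose against PBS 87 were also higher against DNase_ATEV and 210 against NTEV, and of the 221 that fell 6 and 30 were also lower. These comparisons share the ATEV libraries, and their fold changes correlated at 0.726 and 0.609, against 0.507 and 0.504 between simulated groups without change. Those simulated groups shared 0 called genes, but they held no changed genes, so that count is no measure for genes that are called. Fold changes against the shared PBS libraries correlated across the 17051 genes, which are not independent replicates, at 0.687 between ATEV and NTEV, 0.672 between ATEV and DNase_ATEV and 0.564 between NTEV and DNase_ATEV. Unchanged groups simulated with a shared PBS group gave 0.494, 0.503 and 0.495. All libraries, PBS included, were drawn anew there and each gene independently, so correlated genes were not represented. The covariances were 0.183, 0.154 and 0.104, against 0.0432, 0.0436 and 0.0428 in the simulation. All 9 genes called in NTEV also rose in ATEV against PBS. The simulation shared at most 1, but without changed genes it could hardly share more, so it does not measure this overlap. With 3 controls that cannot be split into groups of at least 2, part of the excess, and of the shared calls, may come from the shared PBS libraries.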

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

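The counts of called genes moved with the method and with single libraries. Over the fits that left out a library they lay between 228 and 1360 for ATEV against PBS, 0 and 58 for NTEV against PBS, 0 and 9 for DNase_ATEV against PBS, 45 and 117 for ATEV against DNase_ATEV, 169 and 641 for ATEV against NTEV, and 155 and 671 for any difference. The counts of called lists lay between 16 and 20, 10 and 16, 15 and 18, 15 and 20, and 14 and 19 in the same order of comparisons. DESeq2 called 1346, 254, 255, 169 and 683 genes and 1288 for any difference, limma voom 1488, 54, 0, 111 and 966 and 1025, and the fits with no filter 1586, 347, 358, 217 and 800 and 1513. Fits of only the groups compared called 1235, 35, 0, 99 and 91, and a threshold of 0.1 gave 1590, 49, 0, 130 and 737 and 865. RLE factors gave 742, 9, 0, 96 and 432, and a filter of CPM over 1 gave 759, 6, 0, 94 and 435. Shared calls with DESeq2 were 90 for ATEV and NTEV, 144 for ATEV and DNase_ATEV and 102 for NTEV and DNase_ATEV, all against PBS. With an estimated correlation 5, 0, 0, 5 and 6 lists were called, and with fry 11, 0, 4, 5 and 7. The cause of these moves was not tested.

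With the replicate number as a block the count for NTEV against PBS was 23. Libraries with the same number correlated, after group means were removed, between -0.176 and 0.288 over 18 pairs, 9 of them over 0.1. For other pairs the range was -0.368 to 0.349, and 7 of 12 libraries correlated best with their own number. These values do not settle whether the numbers pair the samples. The labels do not say that they do, so the block was used only as an alternative. Of the settings added after seeing the data, the salivary gland score as a covariate gave 19 for NTEV against PBS. Leaving out the most salivary library of each group gave 276 for NTEV against PBS, 397 for DNase_ATEV against PBS, 145 for ATEV against DNase_ATEV and 798 for any difference.

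Direction turned for 2 list results. For the list MHC class II presentation, NTEV vs PBS, the direction differed without NTEV replicate 2 (adjusted p = 0.0492). Over the fits that left out a library its adjusted p lay between 0.0375 (without NTEV replicate 3) and 0.971 (without PBS replicate 2). The stromal list in ATEV against NTEV pointed down without the most salivary libraries (adjusted p = 0.0374). A further 129 uncalled results changed sign. Among list results the settings chosen in advance left 407 the same, 1 stronger and 112 weaker, and leaving out a library 1450, 61 and 48. The added settings left 236 the same, 15 stronger and 8 weaker. Among named genes these were 2014, 30 and 51, then 2737, 9 and 398, then 481, 14 and 29. Called named genes kept their call throughout in 39 of 77 for ATEV against PBS, 0 of 9 for NTEV against PBS, 21 of 35 for ATEV against DNase_ATEV and 26 of 55 for ATEV against NTEV, and all kept their sign.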

Other observations

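In the H2 region of chromosome 17 (GENCODE M21), the genes that lie between the presentation genes did not rise with them in ATEV against PBS. Of 73 tested neighbours that code for proteins of other kinds 0 rose and 2 fell, Notch4 (-0.82 ± 0.14) and Atf6b (-0.36 ± 0.08), with Tubb5 at 0.044 ± 0.09 and Ltb at 0.11 ± 0.15. Class II genes summed to 20190.0 CPM in PBS and 35370.0 CPM in ATEV. B and plasma cell markers summed to 244.3 and 768.6 CPM, macrophage markers to 1565 and 1976 CPM and NK cell markers to 240.2 and 518.7 CPM. The marker sums do not measure how much class II RNA such cells would add, so no conclusion on mixed-in cells is drawn from them. An explanation by reads shared between near-identical H2 genes was also examined and then left out of the tests below. Of the 22 list members outside that family 11 rose and 1 fell.

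For the higher presentation genes in ATEV, all tests were chosen after the results of the comparisons were seen, the limits for the H2 region, the haplotype and an interferon response after the values they concern, so that the outcome of the last could be foreseen. Cells of another type mixed into the sort could raise class II genes, since B cells and macrophages carry them, but with a marker list as covariate the median of the 27 called genes was at its lowest 0.95, with the stromal list, against 1.08 without. As few as 1 of the 27 stayed called in these fits, with the B and plasma cell list or the neutrophil list, so this test could not tell. A change of the whole H2 region is set against by the neighbours' median of -0.056 (bootstrap spread 0.02). All 21 of 21 members on chromosome 17 rose, but an H2 haplotype that expresses H2-Ea is set against by 0 counts of H2-Ea-ps in each ATEV library (at most 3 in any other) and by 7 of 17 members outside the chromosome being called, 6 higher and 1 lower, while haplotypes without that expression were not tested. An interferon response might drive Tap1, yet the 55 members of both interferon lists had a median of 0.0596 (bootstrap spread 0.0539), although a response limited to Nlrc5 and Ciita targets may pass this test by.

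For the marker lists in ATEV, the tests of a smaller plasmacytoid share and of salivary gland RNA were chosen after the results were seen. The limit for the plasmacytoid share was set after the list medians it compares, so its outcome could be foreseen. A smaller share of plasmacytoid cells alone would raise all other types alike. The NK list lay 2.14 above the type 1 conventional list (bootstrap spread 0.30), a difference that restates the pattern and is no separate support. Salivary gland RNA could disturb the scale, yet with the salivary score as a covariate the median of the 25 called markers was 1.62, against 1.71 without, and all 25 stayed called. The sort should exclude CD11b-bearing neutrophils, and a less pure sort in this group may account for S100a8 and Itgam, as may altered cells within the gate, and these counts were not able to separate them.

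For the ribosomal and oxidative phosphorylation genes in NTEV and DNase_ATEV, both tests were chosen after the results were seen, that of length because these short genes were higher, with limits fixed before the tests were run. Transcript length may take part, since the 2676 shortest genes of 13379 lay above the 2676 longest by 0.130 in DNase_ATEV against PBS and by 0.162 in NTEV against PBS, with list medians of 0.293 and 0.324. In both comparisons the values fell between the limits set, nearer the upper one, and the test could not tell. In ATEV against PBS, which the test did not use, the difference was 0.104 with a ribosomal median of 0.121. By longest transcript, the ribosomal genes had a median length of 1200 bases, while the 2676 shortest genes reached up to 2055. Salivary RNA is set against by a ribosomal median of 0.308 with the salivary score as a covariate in DNase_ATEV against PBS.

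For splits of the libraries into other groups, all tests were fixed before they were run. For any difference between the 4 groups, 1 of 100 splits, the real one, gave as many as 409 called genes, and the highest other gave 130, from a split that kept the 3 ATEV libraries together. Splits of the 6 libraries of a comparison numbered 10, too few for a share under 0.05. The real split was the only 1 to give its count of 763 for ATEV against PBS (highest other 0), of 9 for NTEV against PBS (highest other 1), of 96 for ATEV against DNase_ATEV (highest other 0) and of 434 for ATEV against NTEV (highest other 0), while for DNase_ATEV against PBS all 10 gave 0.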
